A study of Homo sapiens with 45 samples.

How the data were processed

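RNA was measured in 45 libraries from day 5 of endoderm or early mesoderm differentiation of the established human line KOLF2.2J: 10 knockouts with 3 clones each and 5 wild-type sets with 3 numbered libraries each. Per the labels' protocols, libraries came from a Watchmaker kit that removes abundant RNA (Polaris depletion) and were sequenced on a NovaSeq X. The submitters' processing notes name STAR, Salmon and featureCounts and the build GRCh38, with no version and no annotation release. The deposited table used for every main result holds whole-number counts of reads per gene from featureCounts, not normalized. A second deposited table holds expected counts per gene estimated by Salmon, which were rounded to whole numbers and used as an alternative. The deposited summary of read assignment holds counts of reads. The TPM table, the transcript tables and the other gene table from Salmon were left out, because they repeat the same libraries in units or at a level that the tests did not need.

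The gene table has 38592 genes, of which 38568 carry a symbol and 34390 are in GENCODE 29, the release used to place the edited exons. Between 21379773 and 36393054 reads per library were assigned to genes, 63.2 to 77.2% of all reads. Reads that were unmapped (1.77 to 5.56%), outside any feature (8.80 to 18.1%), multimapping or ambiguous are named in the summary table alone and stayed out of library sizes and tests. The highest gene took at most 1.50% of the counts of a library. Salmon totals ran from 22456638 to 38113016. Replicate libraries were checked for copies: over the 45 pairs within groups, the chi-square per gene against counting error was 1.62 to 54.3, so none was a copy of another.

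Groups came from the labels. Each knockout was compared with the wild-type set of its experiment in a fit of all groups of that experiment, with edgeR 4.0.16 in R 4.3.3: TMM scaling, the filterByExpr filter and the quasi-likelihood F test, at an adjusted p under 0.05 (Benjamini-Hochberg). Counts were summed per experiment for wild-type endoderm (2 sums) against wild-type mesoderm (3 sums). Standard errors of log2 fold changes come from the fitted F statistic. The 29 gene lists, their members, the comparisons, the tests and the rule for named genes were chosen before the data were examined. Lists were tested with camera of limma 3.58.1 with a preset correlation of 0.01 and again with an estimated correlation, each adjusted over the lists of a comparison. A list that holds the edited gene counts it as a member unless the text says otherwise. Named genes were the edited gene, the 5 largest called changes in each direction, up to 3 called members of each list with at least 2 called members (smallest adjusted p), and any other edited gene that was called. Not every gene that this rule selects, other edited genes included, is named in the text. The largest changes had to reach a mean of 5 CPM over the libraries compared and separate every knockout from every wild-type library. Captions also name members of the plotted lists. A fold against a group without counts was computed against a floor of 3 counts over the group, and ratios to 1 to 3 counts carry a 95% interval that covers counting error only.

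Levels of genes with near-identical copies, among them LEFTY1 and LEFTY2, POU5F1, NANOG, GYPB, the metallothionein genes and the mitochondrially encoded genes with nuclear copies, depend on how shared reads were assigned and are uncertain. Y-linked genes and XIST were left out. Some members of the gene lists are counted in the lists but not reported here by name.

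The test was checked on simulated data with known changes put into 1 knockout per experiment. Counts of all groups were drawn at the depth of the libraries, from the wild-type mean and the spread pooled over the groups of the experiment. At 2-fold, 76.6% of changed genes were recovered in the first endoderm experiment, 72% in the second, and 82%, 79.2% and 84.4% in the 3 mesoderm experiments. At 4-fold the values were 97.9, 95.9, 96, 100 and 100%, at 1.5-fold 72.3, 36.7, 64, 66.7 and 59.2%, and at 1.25-fold 24.4, 2.1, 8, 39.6 and 55.1%. Of the genes simulated without a change, 4 to 9 were called among 17302 to 18279 genes. Only 45 to 50 tested genes were changed at each fold, with directions drawn at random. The check therefore does not cover the scaling in comparisons where most tested genes were called, such as GATA6 (73.0%).

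Alternatives were RLE scaling, DESeq2 1.42.0, no filter on low counts, the Salmon table, a fit of the compared groups alone, a fit of all libraries of a germ layer, and leaving out each library. SOX17 was also tested within lane 7. For the layers, the alternatives were the 15 libraries as replicates, with and without the wild-type number as a block, and leaving out each experiment. A lane term for LHX1 and SOX17 and the lists without the edited gene were added after the data were seen. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9.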

Results

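Transcripts were measured by RNA-seq in cells derived from KOLF2.2J, an established human induced pluripotent stem cell line, at day 5 of differentiation toward endoderm or early mesoderm. The 45 libraries formed 15 groups of 3: 10 knockouts, each homozygous null for 1 transcription regulator and represented by 3 clones, and 5 wild-type sets of 3 numbered libraries. Each knockout was set against the wild-type set of its own experiment. GATA6 and GSC shared the first endoderm set and SOX17 and LHX1 the second, while CITED1 and HOXB8 shared the first mesoderm set, HES6, SP5 and TBXT the second, and MSX1 had the third. Between 21379773 and 36393054 reads per library were assigned to genes, and 24650 to 26545 genes were detected. Levels are means ± SD of 3 libraries in CPM (counts scaled to library size), and log2 fold changes of knockout over wild type carry their standard error. The adjusted p-values come from edgeR's quasi-likelihood test and measure the spread between clones and between wild-type libraries, pooled over the groups of an experiment.

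Termination codon edits in GRCh38 lay in coding exons of 8 genes. They were at chromosome 18, 22171757 to 22171759, in exon 2 of 7 of GATA6; chromosome 14, 94769872 to 94769874, in exon 1 of 3 of GSC; chromosome 8, 54458343 to 54458345, in exon 1 of 2 of SOX17; and chromosome 17, 36940354 to 36940356, in exon 2 of 5 of LHX1. The mesoderm genes had theirs at chromosome X, 72302161 to 72302163, in exon 3 of 3 of CITED1; chromosome 17, 48614480 to 48614482, in exon 1 of 2 of HOXB8; chromosome 2, 170716520 to 170716522, in exon 2 of 2 of SP5; and chromosome 6, 166166760 to 166166762, in exon 3 of 9 of TBXT. Deletions removed 1078 bp of HES6, chromosome 2, 238238836 to 238239913, across exons 1 to 4 of 4, and 3295 bp of MSX1, chromosome 4, 4859854 to 4863148, across exons 1 to 2 of 2.

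The deleted genes were nearly silent in their clones. HES6 had 4 to 10 counts per clone, 0.294 ± 0.126 CPM against 178 ± 1.35 in wild type (log2 -9.22 ± 0.23). MSX1 had 137 to 165 counts per clone, 6.17 ± 0.191 CPM against 403 ± 28.0 (log2 -6.03 ± 0.07). A stop codon need not change a transcript's level, so for the other genes the level does not check the labels. GATA6 mRNA fell from 755 ± 30.2 to 489 ± 44.0 CPM (log2 -0.62 ± 0.09) and SOX17 from 636 ± 108 to 277 ± 89.4 (log2 -1.18 ± 0.18). Transcripts of LHX1 (342 ± 25.9 to 568.5 ± 14.7 CPM), SP5 (435 ± 1.13 to 776 ± 53.7) and TBXT (121 ± 5.94 to 256 ± 10.9) rose, by 0.72 ± 0.12, 0.84 ± 0.05 and 1.10 ± 0.08 on the log2 scale. HOXB8 stood at 83.7 ± 1.41 against 79.5 ± 6.25 CPM (adjusted p = 1.0) and CITED1 at 21.1 ± 0.595 against 26.4 ± 4.27 (adjusted p = 0.0531), while CITED1 passed the test with DESeq2 (0.0323), RLE scaling (0.049) and no low-count filter (0.0233). GSC rose from 433 ± 18.9 to 512 ± 95.6 CPM (log2 0.25 ± 0.09, adjusted p = 0.0288), a call lost without GSC clone 2 (0.172), wild-type library 3 (0.0836) or wild-type library 4 (0.116), with the Salmon table (0.101) and with all endoderm libraries (0.0634).

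**Figure D1:**
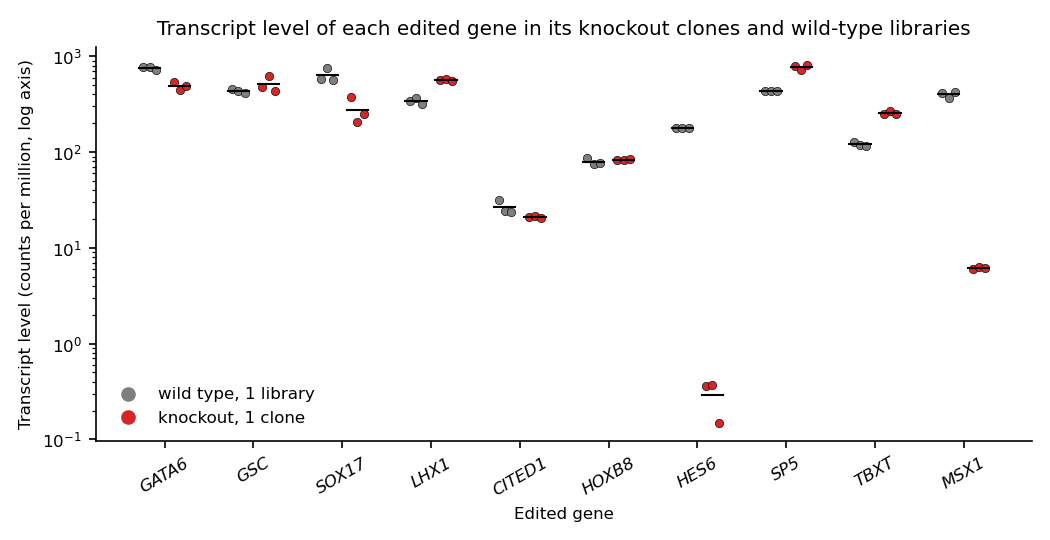
Level of each edited gene (CPM, log axis) in the 3 knockout clones (red points) and the 3 wild-type libraries of the same experiment (gray points), with the mean as a line. The deletions of HES6 (0.294 against 178) and MSX1 (6.17 against 403) stand apart from the termination codon edits, whose transcripts stayed above 20 CPM in every clone.

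Which transcripts day-5 cells lose or gain without each regulator was asked knockout by knockout. The number of genes that differed from wild type ranged from 1 without HOXB8 to 13825 without GATA6.

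**Figure D2:**
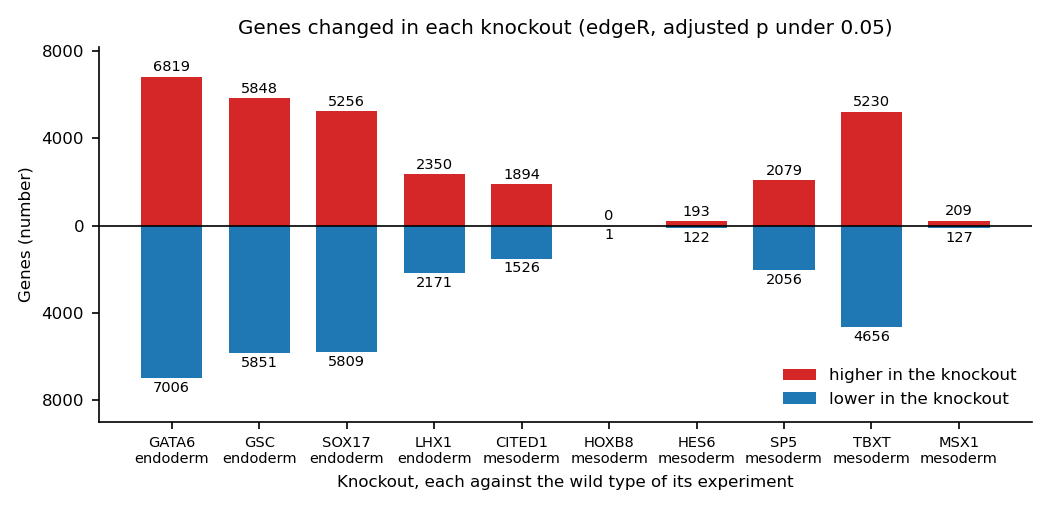
Number of genes higher (red, upward) or lower (blue, downward) in each knockout than in the wild type of its experiment, at an adjusted p under 0.05. Endoderm knockouts of GATA6, GSC and SOX17 and the mesoderm knockout of TBXT changed the most genes (13825, 11699, 11065 and 9886), and HES6 and MSX1 changed 315 and 336. In a fit of HES6 and wild type alone, the HES6 count was 2167.

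Without GATA6, endoderm cells lost most of the transcripts that mark definitive endoderm. HHEX, a homeobox regulator of foregut endoderm, fell from 157 ± 1.47 to 4.09 ± 0.827 CPM (38.6-fold), and PRDM1 from 188 ± 1.56 to 6.21 ± 0.989. The endoderm regulators SOX17 (log2 -4.82 ± 0.20), GATA4 (-4.84 ± 0.11) and FOXA2 (-3.01 ± 0.13) fell, as did FZD5 (-5.11 ± 0.11), a WNT receptor. HNF4A, a hepatic and gut regulator, dropped from 144 ± 4.21 to 0.0878 ± 0.0554 CPM. In their place rose mesenchymal and neural crest transcripts, among them TWIST1 (0.406 ± 0.0949 to 83.6 ± 3.32 CPM), SOX9 (93.2-fold) and the intermediate filament gene VIM (11.8-fold).

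Of 18 measured definitive endoderm genes, 16 fell, GATA6 itself among them, and 1 rose in the GATA6 knockout (18 adjusted over the list alone). The camera adjusted p was 1.85e-21, and 0.0191 with an estimated correlation. Gut tube and hepatic genes fell in 9 of 11 cases with 1 rise, and NODAL targets in 9 of 12 with 2 rises, such as LEFTY2 (log2 -7.96 ± 0.14), an inhibitor of NODAL that has a near-identical copy. Both held with an estimated correlation (adjusted p = 0.0191 and 0.048). Mesenchymal genes (9 rose, 3 fell of 13) and neural crest genes (6 rose, 3 fell of 9) also held (0.0191 and 0.048), although FN1, which encodes fibronectin, fell 15.2-fold. Cholesterol synthesis genes rose in 17 of 18 cases and fell in 1, with CYP51A1 up 3.69-fold, and mitotic cycle genes in 19 of 20, with TOP2A up 3.44-fold. Epithelial genes fell in 12 of 15 cases and rose in 2 (EPCAM 5.93-fold lower, ESRP1 4.27-fold lower), and primitive streak genes split into 7 that fell and 5 that rose of 13. These last 4 lists passed camera with a preset correlation but not with an estimated one (adjusted p = 0.178, 0.238, 0.321 and 0.321), and the primitive streak call was also lost without the low-count filter (0.141).

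Single signalling targets changed as well. The WNT target DKK4 was at 77.3 ± 15.1 CPM against 0.0859 ± 0.0389, DKK1 rose 25.7-fold and LGR5 fell from 128 ± 3.41 to 0.859 ± 0.596 CPM, and WNT targets as a list split evenly (8 rose, 8 fell of 16, camera adjusted p = 0.804). The NOTCH effector HES1 rose 184-fold, and on the log2 scale the BMP target ID3 rose by 3.81 ± 0.10 and the ERK phosphatase gene DUSP6 by 3.46 ± 0.07. Their lists did not pass camera: NOTCH targets (5 rose, 4 fell of 11, adjusted p = 0.0981), BMP targets (7 rose, 3 fell of 12, 0.0752) and FGF and ERK targets (11 rose, 3 fell of 14, 0.0846). INHBB, an activin subunit gene, had no counts in wild type and 47.3 ± 3.74 CPM in the knockout, at least 1260.0-fold higher against a floor of 3 counts over the group. TBXT rose 75.5-fold, to 25.03 ± 7.80 CPM. In all, 13825 of 18928 tested genes changed, 6819 higher and 7006 lower, and 6025 changed at least 2-fold.

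Loss of GSC left cells with fewer definitive endoderm and gut transcripts and more mesenchymal and cholesterol synthesis transcripts. HAPLN1, which encodes a hyaluronan link protein, rose from 0.159 ± 0.0661 to 770.3 ± 47.5 CPM, and the WNT inhibitor gene DKK1 rose from 2.28 ± 0.453 to 156 ± 5.02. The chemokine receptor gene CXCR4 fell from 1173 ± 8.89 to 139 ± 11.8 CPM, and the pioneer factor gene FOXA2 from 252 ± 8.41 to 29.8 ± 4.41. LEFTY2 fell 17.6-fold and NODAL itself 2.47-fold, but NODAL targets did not pass as a list (4 rose, 6 fell of 12, camera adjusted p = 0.255). TFAP2C rose 15.8-fold, WNT5A 51.2-fold and HES1 105-fold.

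Definitive endoderm genes fell in 12 of 18 cases and rose in 4 without GSC, with the GSC transcript itself among the 4. Gut tube and hepatic genes fell in 8 of 11 cases and rose in 1, with HNF4A 3.89-fold lower. Mesenchymal genes rose in 11 of 13 cases and fell in 1, with VIM up 5.76-fold and ZEB2 up 37.9-fold, while FN1 fell 5.21-fold. Cholesterol synthesis genes rose in 17 of 18 cases and fell in 1, with HMGCS1 up 4.83-fold and FDFT1 up 3.18-fold. These 4 lists passed camera with a preset and with an estimated correlation (adjusted p = 0.0267 for the first 3 and 0.0399 for cholesterol synthesis). Epithelial genes fell in 13 of 15 cases, with CDH1, the E-cadherin gene, 7.01-fold lower and CLDN7 8.22-fold lower, all 20 mitotic cycle genes rose, with CDC20 up 2.67-fold, and WNT targets rose in 10 of 16 and fell in 6. For each of these the call was lost with an estimated correlation (adjusted p = 0.138). The same held for endothelial and blood genes (9 rose, 1 fell of 10; 0.173), notochord genes (2 rose, 5 fell of 9; 0.324) and NOTCH targets (6 rose, 4 fell of 11; 0.367). Without GSC clone 2, the endothelial list missed the test with a preset correlation too (0.0784), as it did with DESeq2 (0.0964), the Salmon table (0.0751) and the 2 groups alone (0.0548). So did NOTCH targets with DESeq2 (0.108), no low-count filter (0.344) and the 2 groups alone (0.0548), notochord genes without the low-count filter (0.0722) and WNT targets with all endoderm libraries (0.121). In all, 11699 of 18928 genes changed, 5848 higher and 5851 lower, and 3736 at least 2-fold.

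Without SOX17, definitive endoderm, gut and NODAL-target transcripts fell. FOXA2 dropped from 223 ± 27.15 to 0.281 ± 0.0810 CPM, HNF4A from 147 ± 25.6 to 0.389 ± 0.117 and GATA4 20.8-fold. The NODAL antagonist genes LEFTY1 (2739 ± 445 to 3.86 ± 1.82 CPM) and LEFTY2 (143-fold) fell, and the division of shared reads between these near-identical genes is uncertain. HAPLN1 rose from 0.275 ± 0.155 to 591 ± 95.7 CPM, TWIST1 42.1-fold, the WNT feedback inhibitor gene NOTUM 7.11-fold and the NOTCH effector HES1 96.2-fold. Neither WNT targets (7 rose, 7 fell of 16, camera adjusted p = 0.769) nor NOTCH targets (5 rose, 3 fell of 11, 0.174) passed as a list. LHX1 rose 2.98-fold, while GATA6 fell 1.74-fold and GSC 1.65-fold. LMX1A had 1 count over the knockout group and 40.92 ± 2.535 CPM in wild type, a ratio of 3650.0 (95% counting interval 655 to 144000.0).

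Definitive endoderm genes fell in 14 of 18 cases, SOX17 itself among them, and rose in 2. Gut tube and hepatic genes fell in 8 of 10 cases and rose in 1, and NODAL targets fell in 7 of 12 and rose in 1. Each of these lists held with an estimated correlation (adjusted p = 0.032). Mesenchymal genes rose in 10 of 14 cases and fell in 2 (ZEB2 up 9.02-fold, FN1 down 6.80-fold; 0.115 with an estimated correlation). Notochord genes fell in 6 of 9 cases and rose in 2, neuromesodermal genes fell in 5 of 9 and rose in 2, with GREB1 6.34-fold lower, and mitotic cycle genes rose in 19 of 20, with CCNB1 up 2.17-fold. FGF and ERK targets rose in 10 of 14 cases and fell in 4, with SPRY4, an ERK feedback inhibitor gene, up 2.74-fold and SPRED1 down 4.30-fold. Cholesterol synthesis genes rose in 13 of 18 cases and fell in 1. For these 5 lists the call rested on the preset correlation (adjusted p = 0.172, 0.192, 0.27, 0.369 and 0.454 with an estimated correlation). Epithelial genes fell in 12 of 15 cases and rose in 2, a list call lost with an estimated correlation (adjusted p = 0.682) and without wild-type library 2 (0.0518). Neural crest genes rose in 6 of 10 cases and fell in 3 (0.192), a call lost without clone 1 (0.0579) or wild-type library 1, 2 or 4 (0.0872, 0.0732 and 0.0582), within lane 7 (0.0792), with lane as a term (0.085) and with the Salmon table (0.0692). In all, 11065 of 19003 genes changed, 5256 higher and 5809 lower. The clones and wild-type libraries were sequenced on several lanes, and the libraries of lane 7 alone (2 against 2) gave 8502 genes.

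**Figure D3:**
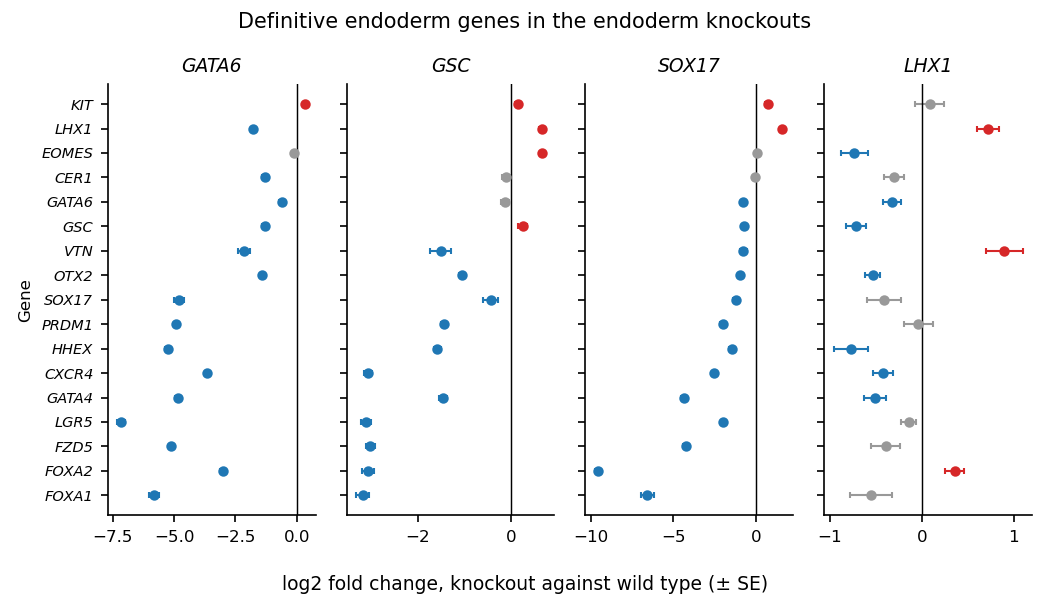
Fold change on the log2 scale (± SE, 3 clones against 3 wild-type libraries) of definitive endoderm genes in the 4 endoderm knockouts, each panel with its own axis range; red and blue points rose or fell at an adjusted p under 0.05 and gray points did not pass. FOXA1, FOXA2, FZD5 and LGR5 lie far to the left without GATA6, GSC or SOX17, while the LHX1 panel stays between -0.77 and 0.90.

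The 3 large endoderm knockouts changed many genes in one direction. GATA6 and SOX17, which have different wild-type sets, shared 3965 higher genes and 4401 lower genes, against 1798.9 and 2132.9 for independent lists of those sizes, and 90.7% of the genes called in both went the same way. GSC and SOX17 shared 3667 higher and 3909 lower genes, against 1565.0 and 1789.2, with 92.5% in the same direction. Genes higher in all 3 knockouts numbered 2971 and lower in all 3 numbered 3347, of 18228 tested in each. GATA6 and GSC share wild-type libraries, so their lists are not independent. Their wild-type set was itself lower in cholesterol synthesis genes than the second endoderm set (11 of 18, 0 higher). Whether it contributed to the rise of these genes without GATA6 or GSC was not tested. Against the second set, these genes also rose without SOX17 (13 of 18, 1 fell).

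In the LHX1 knockout, definitive endoderm genes moved less than 1 log2 unit: 4 rose, LHX1 itself among them, and 7 fell of 18 (camera adjusted p = 0.15). GRIK3, a glutamate receptor gene, fell from 22.03 ± 2.74 to 0.502 ± 0.198 CPM, the kidney and mesothelial regulator gene WT1 fell from 6.97 ± 1.46 to 0.398 ± 0.179 CPM, and ZEB2, a repressor of epithelial genes, fell 19.1-fold. CLDN18, a tight junction gene of stomach and lung, rose from 6.29 ± 0.594 to 73.5 ± 1.80 CPM, the NOTCH modifier gene LFNG rose 8.82-fold and KDR, the VEGF receptor gene, 4.74-fold. GSC fell 1.64-fold, FGF8 2.34-fold and NODAL 1.63-fold. PAX6 rose 4.28-fold, while ZIC5 and GATA3 fell 2.28-fold and 3.53-fold.

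NODAL targets fell in 7 of 12 cases (9 adjusted over the list alone), and primitive streak genes fell in 7 of 13 and rose in 1, which was LHX1 itself. Hypoxia and glycolysis genes rose in 9 of 16 cases, with ADM, which encodes adrenomedullin, up 4.91-fold and NDRG1 up 2.30-fold. BMP targets rose in 4 of 12 cases and fell in 2 (ID3 up 3.02-fold, BMPER up 2.34-fold), lateral plate genes fell in 6 of 9 and rose in 1, and mitotic cycle genes rose in 7 of 20. Cholesterol synthesis genes fell in 7 of 18 cases, a list call lost without wild-type library 1 (0.114). All 7 lists passed camera with a preset correlation, and none did with an estimated one (adjusted p = 0.182, 0.298, 0.298, 0.539, 0.335, 0.62 and 0.62). In BMP and cholesterol synthesis genes, the wild-type set of this experiment itself differed from the first endoderm set, opposite to the LHX1 clones. BMP targets were lower in it (4 of 11, 0 higher) and cholesterol synthesis genes higher (11 of 18, 0 lower). Both passed camera with a preset but not with an estimated correlation (adjusted p = 0.395 each). Whether this wild-type set contributed was not tested. In all, 4521 of 19003 genes changed, 2350 higher and 2171 lower. Library quality differed with the group: 74.2% of reads were assigned to genes in the LHX1 clones and 67.1% in wild type, and exonic length explained 5.90% of the rank variance of fold changes. No wild-type library was on lane 5 with the LHX1 clones, so no within-lane value exists. With lane as a term, which rests on 1 SOX17 clone for lane 5, 980 genes changed, and the NODAL, primitive streak, lateral plate and mitotic lists missed the test (0.152, 0.366, 0.152 and 0.971). The genes named above passed in that fit, but they are not all the genes that the naming rule selects. Of those not named above, APOB, PROX1 and AXIN2 changed direction with lane as a term. Leaving out clone 1, 2 or 3 gave 2365, 2301 or 2527 genes and leaving out wild-type library 4 gave 2533. The BMP list was lost without wild-type library 1 (0.117), with the Salmon table (0.0553) or the 2 groups alone (0.0538), and the lateral plate list without the low-count filter (0.1), with all endoderm libraries (0.126) or without clone 1 (0.123), clone 2 (0.0791), wild-type library 1 (0.114) or wild-type library 2 (0.0978).

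Among the mesoderm knockouts, TBXT changed the most genes, and presomitic, lateral plate and endothelial transcripts were among those that fell. MSGN1, a regulator of presomitic mesoderm, fell from 221 ± 2.97 to 0.653 ± 0.0160 CPM, TBX6 from 402 ± 2.97 to 10.6 ± 1.28 and FOXC1 204-fold. The lateral plate genes HAND1 (80.7-fold), PDGFRA (59.3-fold) and FOXF1 (39.1-fold) fell, as did LMO2 (20.7-fold), a regulator of blood and endothelium. RSPO3, a WNT agonist gene, had 2 counts over the knockout group and 112 ± 6.68 CPM in wild type, a ratio of 4580.0 (95% counting interval 1270.0 to 37800.0). SOX2, a neural and pluripotency regulator, rose from 1.05 ± 0.313 to 75.8 ± 11.4 CPM and ZIC1 from 3.97 ± 0.535 to 203 ± 49.7, and EPCAM, an epithelial adhesion gene, rose 32.7-fold.

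Presomitic and paraxial genes fell in 8 of 12 cases without TBXT and rose in 3, among them PAX3 (29.2-fold), while lateral plate and cardiac genes fell in 7 of 11 and rose in 3. Endothelial and blood genes fell in 5 of 9 cases with no rise. Neural ectoderm genes rose in 9 of 11 cases (NES up 2.69-fold), neural crest genes in 6 of 9 with 2 falls (SOX9 up 5.91-fold) and pluripotency genes in 8 of 12 (L1TD1 up 4.22-fold, TDGF1 up 9.39-fold). These 6 lists held with an estimated correlation (adjusted p = 0.00835, 0.00835, 0.0155, 0.00835, 0.0144 and 0.04). All 14 measured epithelial genes rose (0.146 with an estimated correlation) and all 20 mitotic cycle genes fell, with PLK1 2.21-fold lower (0.105). Mesenchymal genes fell in 9 of 14 cases and rose in 4, with SNAI1, which represses epithelial genes, 9.54-fold lower (0.0803). Notochord genes rose in 5 of 6 cases, TBXT itself among them, and fell in 1 (0.0801). Intermediate mesoderm genes fell in 3 of 6 cases and rose in 2 (0.0807), a list call also lost with DESeq2 (0.355) and without the low-count filter (0.499). Definitive endoderm genes split into 7 that fell and 6 that rose of 14 (0.0807), a call lost with DESeq2 (0.08), without the low-count filter (0.417) or without clone 1 (0.0853). Mitochondrially encoded genes rose in 12 of 13 cases (0.728), a call lost with the Salmon table (0.0779), the 2 groups alone (0.0541) or all mesoderm libraries (0.328), or without clone 2 (0.0923) or wild-type library 3 (0.0529), and their share of reads was 0.328% in the clones and 0.249% in wild type.

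HOX genes of paralog groups 5 to 13 rose in 12 of 17 cases without TBXT and fell in 2, with HOXA7 up 5.23-fold and HOXC9 up 15.5-fold, FGF and ERK targets fell in 9 of 14 and rose in 2, with DUSP6 6.49-fold lower, and hypoxia and glycolysis genes rose in 12 of 16, with ENO2 up 3.81-fold. All 3 calls were lost with an estimated correlation (adjusted p = 0.35, 0.116 and 0.35). Of the 7 other edited genes measured, 2 rose and 5 fell, among them MSX1 (3.04-fold higher), CITED1 (8.53-fold lower) and SP5 (1.39-fold lower). In all, 9886 of 18328 genes changed, 5230 higher and 4656 lower, and 3091 at least 2-fold.

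Without SP5, a WNT-responsive repressor, anterior HOX and presomitic transcripts fell. HOXB1 fell from 123 ± 4.03 to 9.54 ± 1.12 CPM and HOXD1 4.27-fold. FOXC1 fell 4.27-fold, the NOTCH ligand gene DLL1 2.19-fold and MSGN1 1.81-fold. The WNT feedback gene RNF43 rose from 47.6 ± 1.10 to 91.75 ± 4.345 CPM and BAMBI 1.87-fold. PRRX1, a mesenchymal homeobox gene, rose from 0.188 ± 0.0614 to 14.1 ± 2.92 CPM, and IGFBP5 fell from 99.99 ± 7.39 to 2.56 ± 2.32.

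HOX genes of paralog groups 1 to 4 fell in 11 of 12 cases and rose in 1, and presomitic and paraxial genes fell in 8 of 12 with no rise (adjusted p = 0.0088 for each with an estimated correlation). WNT targets, of which SP5 is 1, rose in 9 of 16 cases and fell in 3 (0.017), but without SP5 itself (8 rose, 3 fell of 15) the call was lost with an estimated correlation (0.0504). NOTCH targets fell in 10 of 13 cases (HES4 4.20-fold, HEY2 1.92-fold), NODAL targets rose in 4 of 7 and neural ectoderm genes fell in 5 of 11 and rose in 1 (ZIC2 2.14-fold lower); these 3 passed with a preset but not with an estimated correlation (0.0501 each). Unfolded protein and amino acid stress genes rose in 14 of 17 cases, with CHAC1, a glutathione-degrading enzyme gene, up 2.89-fold, PSAT1, a serine synthesis gene, up 1.77-fold and ATF4, which encodes the stress regulator, up 1.54-fold (0.143). BMP targets rose in 6 of 12 cases and fell in 2, with ID2 up 3.16-fold and ID1 down 1.96-fold (0.206), and posterior HOX genes fell in 7 of 17, with HOXC8 3.98-fold lower (0.146). Amnion genes rose in 4 of 7 cases and fell in 1 (0.0592). Primitive streak genes (4 rose of 12; 0.0501) and neuromesodermal genes (8 rose, 3 fell of 15; 0.22) passed with a preset correlation only while SP5 was counted (0.107 and 0.111 without it), and both calls were lost without clone 1 (0.0572 and 0.545). The wild-type set of this experiment itself differed from the first mesoderm wild-type set, in the direction opposite to the SP5 clones. Anterior HOX genes (10 of 12, 1 lower) and presomitic genes (8 of 12, 3 lower) were higher in it, and WNT targets (12 of 16, 2 higher) lower. These passed camera with a preset but not with an estimated correlation (adjusted p = 0.157, 0.317 and 0.252). This wild-type set differed from the third mesoderm set in the same directions. Anterior HOX genes (10 of 12, 2 lower) and presomitic genes (8 of 12, 2 lower) were higher in it, and WNT targets (11 of 16, 3 higher) lower. Whether this wild-type set contributed was not tested. In all, 4135 of 18328 genes changed, 2079 higher and 2056 lower.

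Few genes were called for the HES6 knockout in the fit of its experiment, with lower NOTCH, neural and presomitic transcripts and higher glycolysis transcripts. FOXC1 fell from 51.5 ± 1.24 to 30.4 ± 3.27 CPM, ZIC1 3.41-fold, FOXB1 2.31-fold and the guidance cue gene NTN1 2.39-fold. PDK1, a kinase gene that restrains pyruvate oxidation, rose from 130 ± 1.71 to 262 ± 11.7 CPM, LDHA, the lactate dehydrogenase gene, 1.73-fold and P4HA1 1.87-fold. ID2 rose 1.66-fold, WNT5B 1.45-fold and CHAC1 2.56-fold, and HOXC5 fell 1.62-fold.

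Hypoxia and glycolysis genes rose in 8 of 16 cases without HES6 (13 adjusted over the list alone), neural ectoderm genes fell in 3 of 11 and presomitic genes fell in 5 of 12, all with an estimated correlation too (adjusted p = 0.0033, 0.0033 and 0.0232). NOTCH targets fell in 4 of 13 cases (0.00239), but HES6 is 1 of the 4. Without HES6 itself, 3 of 12 NOTCH targets fell and the list still passed (0.0454 with an estimated correlation). Of 8 measured edited genes of the study, HES6 alone fell (0.00239), and the other 7 gave no call as a list (camera adjusted p = 0.835). Unfolded protein and amino acid stress genes rose in 5 of 17 cases (12 adjusted over the list alone; 0.0919), amnion genes rose in 1 of 7 (0.0574) and p53 response genes fell in 2 of 20, BTG2 among them (0.202). With a preset correlation alone passed neuromesodermal (3 rose of 15), BMP (2 rose of 12), epithelial (1 rose of 14), anterior HOX (3 fell of 12), posterior HOX (2 fell of 17) and mitochondrially encoded genes (0 of 13 called; 0.202, 0.211, 0.202, 0.202, 0.249 and 0.591). The mitochondrial call was lost without clone 1 or 2 (0.0771 and 0.277), without wild-type library 2 or 3 (0.093 and 0.156), with the Salmon table (0.0722) and with all mesoderm libraries (0.246). Hypoxia and glycolysis genes also rose against this wild-type set in the TBXT clones (12 of 16) and, short of a list call, in the SP5 clones (6 rose, 2 fell). The set was itself lower than the first mesoderm wild-type set in these genes (12 of 16, 2 higher). It was higher in presomitic genes (8 of 12, 3 lower) and NOTCH targets (8 of 12, 1 lower). Against the third mesoderm set it was also lower in hypoxia and glycolysis genes (9 of 16, 3 higher). Presomitic genes (8 of 12, 2 lower) and NOTCH targets (10 of 12, 2 lower) were again higher in it. Whether this wild-type set contributed to the HES6 changes was not tested. In all, 315 of 18328 genes changed, 193 higher and 122 lower. The count fell to 117, 163 or 114 without clone 1, 2 or 3, to 95 or 127 without wild-type library 2 or 3, and to 87 higher and 48 lower genes without wild-type library 1. It was 503 with DESeq2, 745 without the low-count filter and 2167 with the TBXT and SP5 clones left out of the fit. The biological coefficient of variation, a measure of spread between replicates, was 6.44% in the main fit and 2.81% without those clones. The main count thus depends on the spread of the TBXT and SP5 clones.

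**Figure D4:**
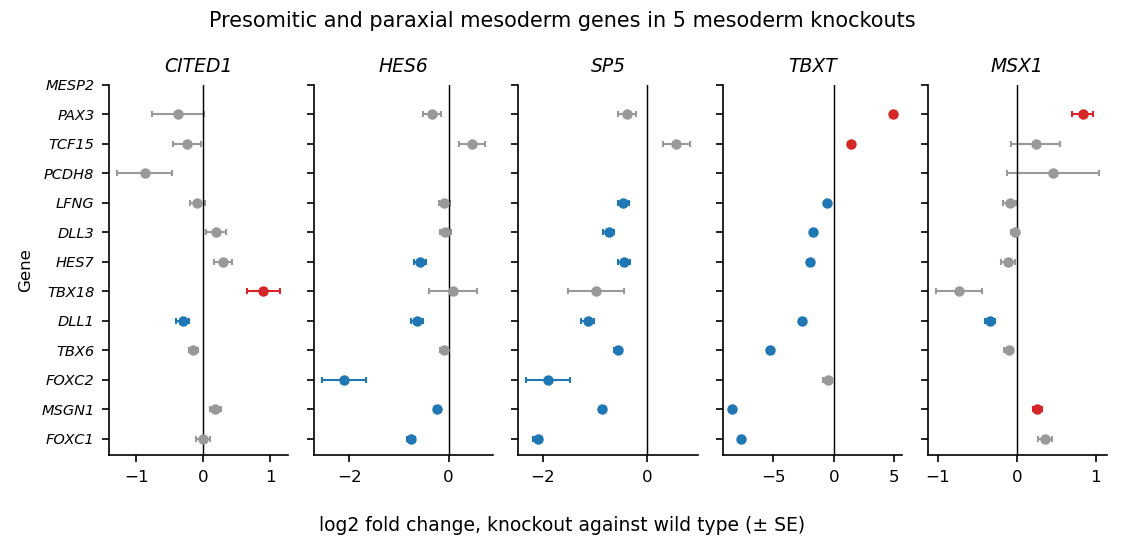
Fold change on the log2 scale (± SE, 3 clones against 3 wild-type libraries) of presomitic and paraxial mesoderm genes in 5 mesoderm knockouts, each panel with its own axis range; red and blue points rose or fell at an adjusted p under 0.05, gray points did not pass, and genes with 3 or fewer counts in a group are left out. FOXC1 lies at -7.67 without TBXT, at -2.10 without SP5 and at -0.76 without HES6, and MSGN1 at -8.38 without TBXT and -0.86 without SP5.

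Loss of MSX1 raised intermediate mesoderm and amnion transcripts. OSR1, a regulator of intermediate mesoderm, rose from 12.2 ± 1.80 to 29.4 ± 1.29 CPM, PRRX1 from 35.1 ± 1.995 to 79.6 ± 11.7 and RSPO3 from 7.59 ± 1.003 to 21.2 ± 4.84. GATA2 rose from 5.57 ± 0.331 to 11.1 ± 0.0745 CPM, GATA3 1.71-fold, PAX2, a kidney lineage regulator, 1.55-fold and TBX3 1.46-fold. LMX1B rose 2.09-fold and the BMP antagonist gene NOG 1.69-fold. ABCG1, a cholesterol exporter gene, fell 2.29-fold and DCBLD1 1.60-fold.

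Intermediate mesoderm genes rose in 4 of 7 cases and amnion and trophoblast genes in 3 of 7, both also with an estimated correlation (adjusted p = 0.0445 each). Posterior HOX genes rose in 4 of 14 cases (10 adjusted over the list alone; HOXB9 1.22-fold, HOXA5 1.53-fold) and lateral plate genes in 5 of 11, which were lost with it (0.114 and 0.12). BMP targets rose in 5 of 12 cases, MSX2 1.30-fold among them, and the 1 that fell was MSX1, so the median was above 0 while the mean and camera pointed down (0.114). Without MSX1 itself, the other 11 BMP targets passed camera upward (adjusted p = 5.59e-10, and 0.0714 with an estimated correlation). Another 11 lists, with at most 4 members risen and 3 fallen, passed with a preset correlation only (adjusted p from 0.114 to 0.42 with an estimated one). In all, 336 of 17550 genes changed, 209 higher and 127 lower, and 24 at least 2-fold. Without clone 2 the count was 568, and without wild-type library 1, 2 or 3 it was 141, 126 or 221. With all mesoderm libraries in the fit 94 genes changed, and the call of MSX2 was lost (0.0657).

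The CITED1 knockout changed many genes by small amounts. DKK4, a WNT inhibitor gene, rose from 5.79 ± 0.547 to 27.4 ± 1.41 CPM, APCDD1, another, rose 1.52-fold, and the tail bud regulator CDX1 1.48-fold. HOXA9 rose from 8.44 ± 0.801 to 23.2 ± 0.826 CPM and HOXD9 2.35-fold, while HOXB3 fell 1.34-fold. ESRP1, an epithelial splicing factor gene, fell 8.30-fold from a low level (2.90 ± 0.525 CPM), and POU5F1, a pluripotency gene with processed copies, fell 2.48-fold. DHCR7, which encodes an enzyme of late cholesterol synthesis, rose 1.64-fold.

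Cholesterol synthesis genes rose in 12 of 18 cases without CITED1 (14 adjusted over the list alone), HOX genes of groups 1 to 4 fell in 6 of 12, those of groups 5 to 13 rose in 6 of 16 and WNT targets rose in 4 of 16 and fell in 1. Epithelial genes fell in 7 of 11 cases, unfolded protein stress genes fell in 7 of 17 and rose in 1, hypoxia and glycolysis genes fell in 7 of 16 and rose in 2, with P4HA1 1.87-fold lower, and mitochondrially encoded genes fell in 4 of 13. Each list passed camera with a preset correlation (adjusted p from 1.9e-07 to 0.0126) and none with an estimated one (adjusted p from 0.563 to 0.594), and the hypoxia list was also lost without clone 3 (0.137) or with all mesoderm libraries (0.0529). In all, 3420 of 17647 genes changed, 1894 higher and 1526 lower, and 407 at least 2-fold. Without clone 2, the 1 library on lane 1, 2192 genes changed, and 2194 or 2147 changed without wild-type library 3 or 4.

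The HOXB8 knockout was close to wild type. The 1 gene that changed, of 17647, was the p53-regulated long noncoding RNA PURPL, which fell from 52.5 ± 2.56 to 22.3 ± 6.21 CPM (log2 -1.23 ± 0.15, adjusted p = 0.0087), a call lost without clone 2 (0.101), clone 3 (0.0737) or wild-type library 1 (0.0825). In the main fit, an unadjusted p under 0.05 was reached by 784 of the 17647 genes, fewer than the share of 0.05 that no change at all would give. Without clone 1 it was reached by 1612 of 17995 genes and with all mesoderm libraries by 1380 of 19638, both above that share. With any other library left out it was reached by 396 to 813 genes. DESeq2 called 4 genes and the fit without the low-count filter 104. Without clone 1 the count was 11, without wild-type library 3 it was 2 and without clone 2, clone 3 or wild-type library 1 it was 0. No member of any list passed the test, and lists that passed camera with a preset correlation, such as unfolded protein stress genes (17 measured, adjusted p = 3.16e-09), did not with an estimated one (0.633; 0.512 to 0.889 over the 7 lists).

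**Figure D5:**
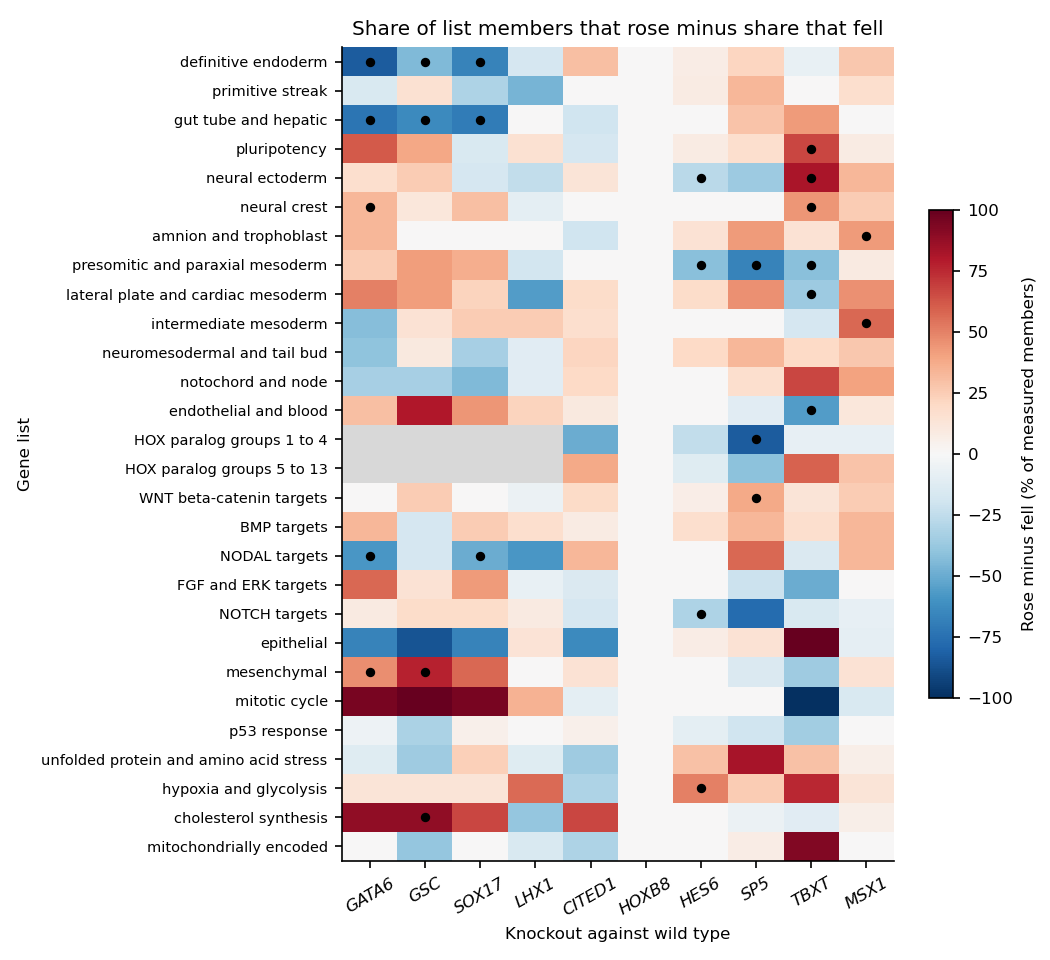
Percent of the measured members of each gene list that rose minus the percent that fell (color) in each knockout, with a black dot where camera gave an adjusted p under 0.05 with an estimated correlation; gray cells had fewer than 3 measured members. Definitive endoderm and gut genes are blue with a dot for GATA6, GSC and SOX17, and presomitic genes are blue with a dot for HES6, SP5 and TBXT. HES6, SP5 and TBXT share 1 wild-type set, which was itself higher in presomitic genes than the other mesoderm sets.

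Wild-type endoderm and mesoderm differed across much of the transcriptome, with the 2 endoderm and 3 mesoderm sets as the replicates (means ± SD of 2 and 3 sums). EOMES, a regulator of endoderm entry, was at 666 ± 3.25 CPM in endoderm and 0.117 ± 0.0395 in mesoderm, and CER1, a NODAL and BMP antagonist gene, at 7716 ± 51.0 and 0.0284 ± 0.0391. In mesoderm, TBXT was at 139 ± 19.1 CPM against 0.255 ± 0.102, the WNT effector LEF1 at 745 ± 95.5 against 0.362 ± 0.0482 and the cadherin gene CDH11 at 1137 ± 229 against 0.151 ± 0.0163. CDX2, a regulator of posterior identity, had no counts in endoderm and 319 ± 18.9 CPM in mesoderm, at least 18400.0-fold higher against a floor of 3 counts over the group. Every edited gene differed in the direction of the layer it was edited in, with GSC at 455 ± 27.2 CPM in endoderm and 1.61 ± 1.58 in mesoderm, and SP5 at 12.4 ± 2.55 and 444.5 ± 65.8.

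All 18 definitive endoderm genes were higher in endoderm and so were 11 of 12 NODAL targets and 14 of 15 epithelial genes, while neuromesodermal genes were lower in 12 of 16 cases and higher in 2, mesenchymal genes lower in 12 of 15 and higher in 3, and all 12 HOX genes of groups 1 to 4 and all 20 mitotic cycle genes were lower. Each passed camera with a preset correlation and none with an estimated one (adjusted p = 0.0632 for the definitive endoderm, NODAL, neuromesodermal and mesenchymal lists, 0.122 for the epithelial list and 0.1 for the HOX and mitotic lists). Another 14 lists passed with a preset correlation only (0.0906 to 0.401). In all, 9887 of 23061 genes differed, 5179 higher in endoderm and 4708 lower. Without the first or the second endoderm set 5006 or 4397 genes differed, with 1 endoderm sum assumed to vary like the mesoderm sums, and 16863 did with the 15 libraries as replicates.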

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

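The lane term, the lists without the edited gene and the comparisons of wild-type sets were tests chosen after the data were seen. The counts of changed genes for GATA6 (13250 to 13651 with a library left out), GSC (10740 to 11969), SOX17 (9721 to 11248), SP5 (2849 to 5165) and TBXT (8989 to 9496) stayed within 1.5 times the reported value under every alternative. With a library left out the counts were 2147 to 3496 for CITED1, 95 to 163 for HES6, 0 to 11 for HOXB8, 2301 to 4525 for LHX1 and 126 to 568 for MSX1, and 4397 to 11479 for the layers with an experiment left out. With all libraries of the layer the counts were 5419 for CITED1, 6840 for LHX1, 94 for MSX1 and 2 for HOXB8; without the low-count filter they were 745 for HES6, 104 for HOXB8 and 682 for MSX1. DESeq2 gave 503 for HES6 and 4 for HOXB8, and the 2 groups alone gave 2167 for HES6. With lane as a term LHX1 had 980 genes; APOB (-0.31), PROX1 (0.17), AXIN2 (0.046) and the epithelial list (signed -log10 p of -2.74) changed direction. Other lists changed direction (HOXB8 list: epithelial) without HOXB8 clone 3 (0.075; -3.23 to 0.075 over the libraries left out), for MSX1 without wild-type library 1 (mitochondrially encoded, 2.62; -2.352 to 2.62), and without the edited gene for MSX1 (BMP targets 10.2, edited genes 3.88) and HES6 (edited genes 0.093), the last 3 because the edited gene carried the list. For the other moves the cause was not tested. Over all alternatives, 8683 gene values kept their direction and call, 419 lost the call, 3 gained it and 3 reversed; for lists these numbers were 3818, 233, 90 and 6.

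With the 15 wild-type libraries as replicates 16863 genes differed between layers, and 16666 with the wild-type number as a block. The numbers did not pair the libraries: deviations of 22 pairs with the same number correlated at -0.296 to 0.227, and 2 were over 0.1, against 16 of 68 pairs with different numbers.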

Other observations

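The lane-number and mesoderm-balance tests and the comparisons of wild-type sets were tests chosen after results were seen. Wild-type mesoderm differed between experiments: 11124 genes between the CITED1 and HES6 sets (named here by an edited gene of the experiment), 9892 between the CITED1 and MSX1 sets and 12676 between the HES6 and MSX1 sets. The endoderm sets differed in 799 genes, in a fit of 6 libraries with a biological coefficient of variation of 9.77%, against 9 libraries and 5.18% for mesoderm, so the counts of the layers are not comparable. Unfolded protein and amino acid stress genes were higher in the MSX1 set than in the CITED1 set (14 of 17, adjusted p = 0.00092 with an estimated correlation) and the HES6 set (15 of 17, 0.0039), and hypoxia and glycolysis genes were lower in the HES6 set than in the CITED1 set (12 of 16, 0.0205).

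These wild-type differences were weighed against 3 explanations. The CITED1 and HES6 sets carry one lane number, yet had 87.8% of the most genes called between sets on different lane numbers, which argues against the lane number. Exonic length explained at most 3.17% of the rank variance, which argues against length bias. Another balance of mesoderm kinds may contribute: in 2 of the 3 pairs of sets, those with the MSX1 set, presomitic genes were lower there and lateral plate genes higher (with a preset correlation; 0.278 and 0.066, and 0.0786 and 0.0602, with an estimated one). Other differences between experiments, such as the day of culture, stay open.

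HES6 and SP5 knockouts shared 138 higher and 104 lower genes, and 4 called in both went opposite ways. Chance values of the shared wild-type libraries would bring a covariance up to 0.0094 in 20 simulations; the covariance was 0.034, 3.63 times that, although the correlation (0.535) was close to the simulated mean (0.496). The 242 shared genes moved in the MSX1, HOXB8 and CITED1 knockouts, which have other wild-type sets, by 7.24, -24.8 and -31.3% of their median in the HES6 knockout. Of these genes, 62.82, 17.65 and 36.13% went in the same direction. The genes were chosen by their calls in HES6 and SP5, which raises the HES6 median. A change of that size common to edited lines is thus argued against, but a small one is not excluded. In the TBXT knockout, which shares the wild-type set of HES6 and SP5, the 242 genes moved by 106.9%, with 66.5% in the same direction. Over all genes, the covariance of HES6 and TBXT was 0.0234 (highest simulated 0.0093) and that of SP5 and TBXT 0.0699 (0.0095), while their correlations (0.155 and 0.243) lay under the simulated means (0.495 and 0.497). No value without change was computed for the 242 genes, so whether TBXT takes part stays open. A response shared by HES6 and SP5, or a difference of this wild-type set from its clones beyond counting and replicate spread, may each contribute and stay open.

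The loss of endoderm transcripts without GATA6, GSC or SOX17 was set against 2 explanations. A smaller share of otherwise unchanged endoderm cells would lower endoderm-specific genes alike, if the cells in their place expressed none of them. Their log2 changes instead had interquartile ranges of 3.45, 1.99 and 3.23, against 0.892 without LHX1, and 155 of 591 were higher without GSC. The genes were chosen against wild-type mesoderm alone, so other cells that express some of them could widen the range. A smaller share of endoderm cells is therefore not excluded. A switch to the wild-type mesoderm programme cannot be told apart from other fates: mesoderm-specific genes crossed a median of 24.5% of the distance to mesoderm without GATA6, 13.4% without GSC and 13.0% without SOX17. Bulk libraries do not show whether all cells moved part of the way or some cells all of it.

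For each knockout and each pair of wild-type sets, 1 of the 10 splits of the 6 libraries, the real one, gave as many genes: 13825 for GATA6, 11699 for GSC, 11065 for SOX17, 4521 for LHX1, 3420 for CITED1, 1 for HOXB8, 315 for HES6, 4135 for SP5, 9886 for TBXT and 336 for MSX1. The highest of the other splits was 0 in each. Every other split puts libraries of both kinds in each group, so a real difference widens the spread and hinders calls. The values of 0 are therefore no support, and 10 splits are too few for a share under 0.05.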
